A study of Mus musculus with 8 samples.

How the data were processed

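The data were 8 expression arrays of mouse epididymal fat, 4 from wild-type mice and 4 from mice transgenic for human IL-37. Per the labels' protocols, total RNA was amplified as whole-transcript cDNA, labelled with biotin and hybridised to single-colour arrays. The deposited values were log2 expression per probe set, and the submitters' processing notes name RMA, a procedure that corrects background, equalises the arrays by quantiles and summarises probes. Its settings, its version and the array annotation behind it were not given in the sources used here. Quantile normalisation makes array distributions alike, so a shift shared by most genes would not be seen, and probe sets near the background understate differences. No detection calls were used here.

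Of 35556 probe sets, 21218 had 1 gene symbol, 1881 had several and 12457 had none in the annotation used. Symbols were taken through the Entrez identifier for 21185 probe sets, with the gene table of assembly GRCm38.p6, which also served to find biotypes, host genes and neighbours. For each gene the probe set with the highest mean over all arrays was kept, which left 18820 genes, 1386 of which had more than 1 probe set. 539 probe sets repeated the 8 values of another exactly and were counted once wherever all probe sets were compared.

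Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no filter, Benjamini-Hochberg threshold 0.05). Differences are transgenic minus wild type. Gene lists were tested with camera at a preset correlation of 0.01, over 34 of 35 lists with at least 5 measured members. The red blood cell list had 3 measured members and was not tested. Each list was also tested with an estimated correlation, with fry and by an exact two-sided permutation of its array means over 70 assignments. Groups, these 35 gene lists, the main model and the rule for named genes were fixed before the data were examined, and 3 more lists were written after. The rule took the 10 largest differences each way among genes past the threshold with groups that did not overlap (leaving out model, clone and small nucleolar names), a panel of inflammatory and metabolic genes, and the 4 members of each passing list, or 2 of each other list, with the lowest p.

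The alternatives were a second quantile normalisation, centring on medians, filters at the 25th percentile and the median gene, other treatments of probe sets, a trended and robust prior, array weights, blocks for replicate number, plate row and plate column, leaving out arrays, and other thresholds. Removal of wild-type replicate 3 and transgenic replicate 4 together was added after the data were seen. The direction of a list across settings was first taken from camera with the median as its value. It was changed to the sign of the mean after the results were seen, which lowered the number of sign changes among lists.

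The steps were tested on simulated data with 200 changed genes among 18820 and the same 4 against 4 design. Of 50 genes each changed by 0.5, 1, 2 and 3 log2 units, 46%, 88%, 96% and 98% were called. In all 178 were called, 14 of them unchanged. No list was called without a change, but the simulated genes were independent, unlike those of a tissue. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.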

Results

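Gene expression was measured in epididymal white adipose tissue, the visceral fat pad beside the testis, of male C57BL/6 mice. All mice ate a high-fat diet with 45% of its energy from fat for 16 weeks, after 2 weeks on a low-fat diet with 10%. 4 arrays came from wild-type mice and 4 from mice carrying a transgene for human interleukin-37 (IL-37), a cytokine of the IL-1 family known to restrain innate inflammation. The values were log2 expression levels of 35556 probe sets, from which 18820 genes were tested. Array medians over all probe sets lay between 5.97 and 6.04. Pearson correlations across the 18820 genes, which are not independent replicates, ran from 0.980 to 0.996 within groups and from 0.971 to 0.991 between them. The number of arrays limits the precision. The labels number the arrays as replicates without stating that each came from a separate mouse, so the p-values measure only the spread between these samples. No probe set in the annotation used carried the human transgene, so its level could not be used to check the group labels.

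The design addressed 1 question, how the fat of obese IL-37 transgenic mice differed from that of obese wild-type mice. The transgenic fat had more RNA for Pck1, the phosphoenolpyruvate carboxykinase that supplies glycerol for fat storage, and for Slc2a4, the insulin-responsive glucose transporter. It had less RNA for Trem2, a lipid receptor of macrophages, and for several enzymes of cholesterol synthesis. The Trem2 call was near the threshold (limma adjusted p = 0.0454) and ended on removal of any of 7 arrays out of 8. Retnla and Cd163, genes of alternatively activated and resident macrophages, were higher. In all, 390 genes were higher and 239 lower in transgenic fat (limma, Benjamini-Hochberg adjusted p at most 0.05), 29 and 46 of them by at least 2-fold. At an unadjusted p of 0.05 the numbers were 2106 and 1772.

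All 629 of these genes had groups that did not overlap, a property shared by 14.0% of all genes where chance gives 2.86%. The counts depended on single arrays: they were 62 higher and 48 lower without wild-type replicate 1, 100 and 61 without wild-type replicate 2, 520 and 668 without wild-type replicate 3, 50 and 32 without wild-type replicate 4, 128 and 81 without transgenic replicate 1, 74 and 62 without transgenic replicate 2, and 148 and 83 without transgenic replicate 4. A letter and a number in the array names, read here as plate row and column, were uneven between groups, with row G alone holding both (2 wild-type arrays and 1 transgenic array). With the row as a block 10 genes were higher and 60 lower, and with the column as a block 44 and 28.

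Among the most elevated genes, Rnase2a, an eosinophil-associated ribonuclease also made by macrophages, rose from 3.97 ± 0.30 to 8.68 ± 1.13 log2 units (SD, n = 4 per group; log2 4.71, SE 0.50, limma adjusted p = 0.00548). Its wild-type mean lay below 4.49, the 25th percentile of gene means, and was not shown to be above background. The measured difference may therefore understate the true one, and no fold is given. Retnla rose from 10.51 ± 0.17 to 11.84 ± 0.24 (log2 1.33, SE 0.13, limma adjusted p = 0.00535). The chemokine gene Ccl17 rose by 1.52 log2 units (SE 0.31) and the acute-phase gene Orm3 by 2.42 (SE 0.51). Fam13a rose by 1.38 (SE 0.11) and Disp2 by 1.72 (SE 0.33). Lyz1 rose by 1.73 (SE 0.22), but it is nearly identical to Lyz2 and its probes may read both. The small nuclear RNA Rnu2-10 rose by 1.5 (SE 0.09) and the small Cajal body RNA Scarna13 by 1.39 (SE 0.23).

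Among the genes that were lower, Gpr50, an orphan receptor related to the melatonin receptors, was 17.7-fold lower, at 10.16 ± 0.54 in wild-type and 6.01 ± 1.17 in transgenic fat (SD, n = 4; log2 -4.15, limma adjusted p = 0.0137). Cck, the gene of the gut and brain peptide cholecystokinin, was 14.1-fold lower (log2 -3.82, SE 0.50). The ubiquitin ligase gene Rnf128 was 8.12-fold lower (log2 -3.02, SE 0.36). Genes of leukocytes in this group were Cd72 (log2 -2.35, SE 0.32), the integrin Itgad (log2 -2.11, SE 0.32), Trem2 (log2 -2.02, SE 0.42) and the prostaglandin D synthase Hpgds (log2 -1.88, SE 0.29). The remaining members of the 10 with the largest decrease were Cdkl4 (log2 -2.14), Kcnj16 (log2 -1.93, with a transgenic mean of 4.37, below the same 4.49, so that its place among the 10 is uncertain) and Il13ra2, the decoy receptor of interleukin-13 (log2 -1.84). Of the 57 named genes past the threshold, 10 passed whichever array was left out (Fam13a, Il13ra2, Lyz1, Otop1, Pck1, Retnla, Rnase2a, Rnf128, Rnu2-10 and Themis) and 47 did not pass without at least 1 array. With the plate row as a block, Kcnj16, Pck1 and Rnu2-10 were the named genes that still passed.

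**Figure D1:**
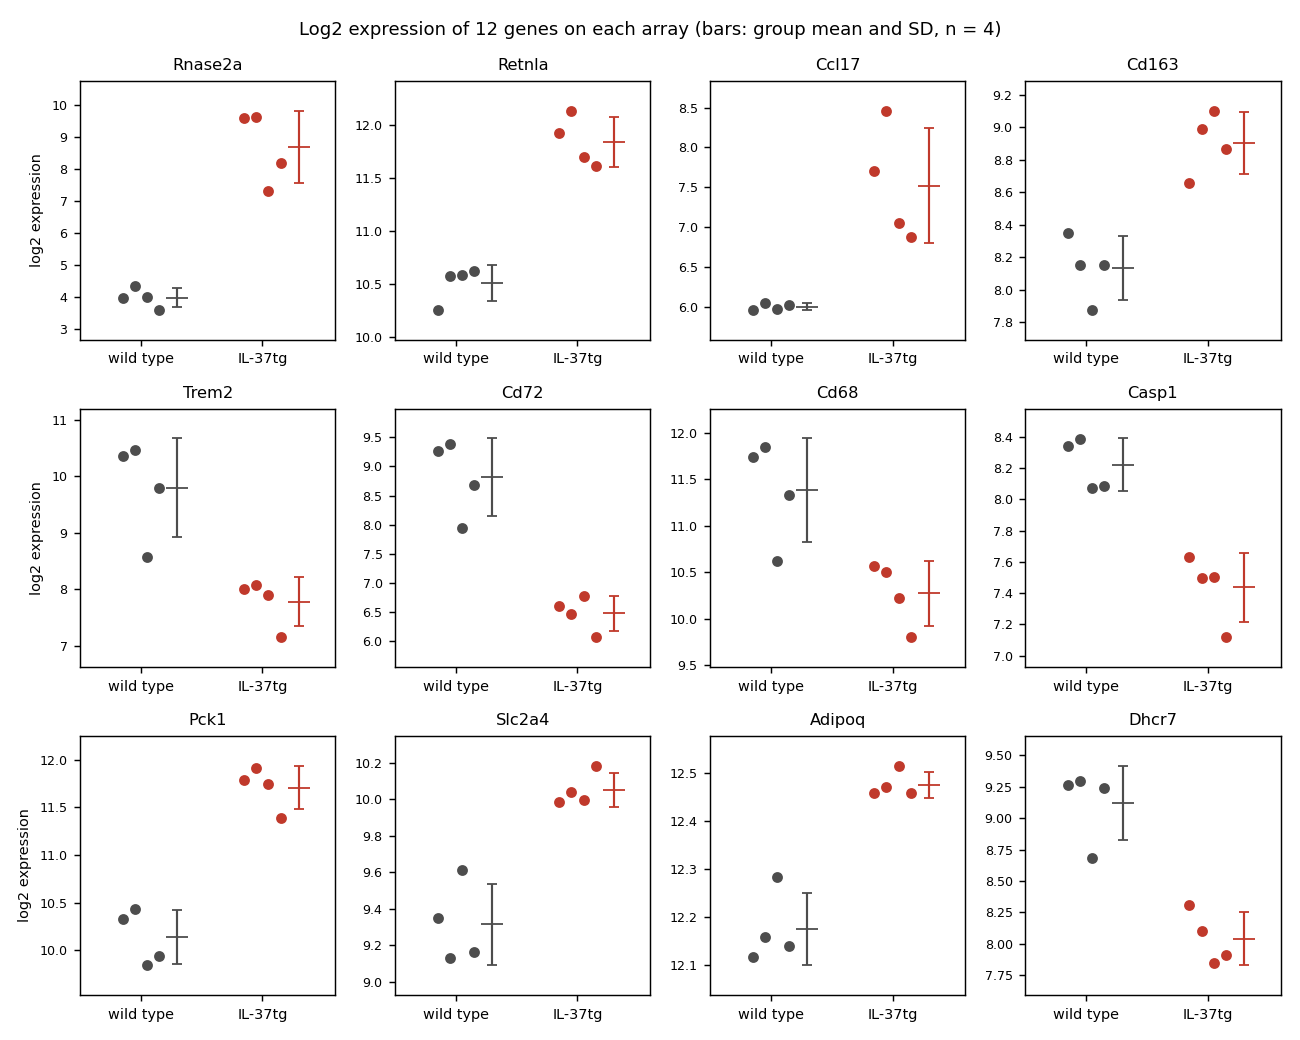
Log2 expression (vertical axes, a separate scale for each gene) of 12 genes on each of 4 wild-type and 4 IL-37 transgenic arrays; points are arrays, and bars give the group mean and SD. Rnase2a lay near 3.97 on wild-type and near 8.68 on transgenic arrays, while the Cd68 groups, which did not pass the test, came close at wild-type replicate 3.

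Macrophage genes as a group ranked lower in transgenic fat. Of 24 general macrophage markers, Cx3cr1 (log2 -0.63, SE 0.11) and Fcgr1 (log2 -1.09, SE 0.23) fell over all genes tested, and 15 fell when adjusted over the list alone. The mean of the list was 9.88 ± 0.41 in wild-type and 9.26 ± 0.20 in transgenic fat (SD, n = 4; exact permutation p = 0.114), and camera gave an adjusted p of 2.11e-10, but the adjusted p was 0.585 with an estimated correlation. Of 18 measured lipid-associated macrophage genes, which mark the macrophages around dying fat cells, Trem2 and Ctsk (log2 -1.25, SE 0.27) fell, and 12 fell when adjusted over the list alone. The mean of this list differed by -0.99 (exact permutation p = 0.0571, camera adjusted p = 2.43e-08, and adjusted p = 0.585 with an estimated correlation). Leaving out 1 array in turn, the calls of Trem2, Ctsk and Fcgr1 were each lost for 7 of the 8 arrays, and that of Cx3cr1 for 6. The macrophage genes Adgre1 (log2 -0.79, adjusted p = 0.163) and Cd68 (log2 -1.11, adjusted p = 0.0750) did not pass by limma, nor did Itgax, the CD11c gene of dendritic cells and some adipose macrophages (log2 -1.23, adjusted p = 0.138). Without wild-type replicate 3 they passed, at -1.08, -1.36 and -1.60. That array had the lowest wild-type values (9.60, 10.62 and 7.98), so its removal was bound to widen the differences and is no support for them.

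The macrophage difference was uneven between arrays. Wild-type replicate 3 had a macrophage mean of 9.32, inside the transgenic values of 8.96 to 9.38. Within plate columns 5, 7 and 9 the macrophage list differed by 0.07, -0.65 and -1.08, and the lipid-associated list by 0.02, -1.11 and -1.55. These columns held few arrays. Column 5 held wild-type replicate 3 and transgenic replicate 2, and column 7 held wild-type replicates 1 and 4 and transgenic replicate 3. Column 9 held wild-type replicate 2 and transgenic replicates 1 and 4. In row G, and equally with the row as a block, the differences were -0.21 and -0.40.

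Resident macrophage genes did not follow the general markers. Of 16 genes, Retnla and Cd163 (log2 0.77, SE 0.12) rose, none fell, and 4 rose and 1 fell when adjusted over the list alone. The list did not pass (mean difference 0.20, camera adjusted p = 0.342), and the difference was 0.12 without wild-type replicate 3, 0.13 without transgenic replicate 2 and 0.09 without the 2 transgenic arrays whose names end in 2. Mrc1, the mannose receptor, differed by -0.37 log2 units (limma adjusted p = 0.124), and passed without wild-type replicate 3, at -0.48. That array had the lowest wild-type value (10.29), so its removal was bound to widen the difference.

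Inflammatory cytokine and chemokine genes ranked lower as a list, though none of the 29 fell alone over all genes tested and Ptgs2, the inducible cyclooxygenase, rose (log2 0.68, SE 0.14). The mean difference was -0.35 (camera adjusted p = 0.000277, and adjusted p = 0.585 with an estimated correlation; adjusted over the list alone, 6 fell and 1 rose). Ccl2 differed by -1.10 (limma adjusted p = 0.184), Ccl3 by -1.66 (adjusted p = 0.0591), Tnf by -0.43 (adjusted p = 0.183), Il6, with both means below 4.49, by -0.21 (adjusted p = 0.322) and Il1b by -0.08 (adjusted p = 0.859). Without wild-type replicate 3, which had their lowest wild-type values (7.82 and 5.97), Ccl3 (-1.93) and Tnf (-0.56) passed, a widening fixed by that choice. Ccl2 was -0.71 without transgenic replicate 4 and -0.14 with the plate row as a block. Of 24 IL-1 family and inflammasome genes, 3 fell: Casp1, the inflammasome protease (log2 -0.79, SE 0.13), Il1r1, the IL-1 receptor (log2 -0.41, SE 0.08), and its accessory chain Il1rap (log2 -0.37, SE 0.08). That list had a camera adjusted p of 0.000485, and an adjusted p of 0.585 with an estimated correlation, with 6 genes falling when adjusted over the list alone. Leaving out 1 array in turn, the Il1rap call was lost for each of the 8 arrays, that of Il1r1 for 6 and that of Casp1 for 4. Il18 (log2 0.25), Il18r1 (log2 0.31), Il1rn (log2 -1.63), Sigirr (log2 -0.08), Nlrp3 (log2 -0.36) and Smad3 (log2 -0.11) did not pass by limma; leaving out 1 array, Il18 ran from 0.13 to 0.33 and Il18r1 from 0.16 to 0.47. With the plate row as a block both lists lost their call, at -0.09 and -0.06, within columns they differed by -0.07, -0.39 and -0.50 and by 0.04, -0.27 and -0.41, and over genes at or above the median gene the differences were -0.56 and -0.42.

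Genes of the fat cell itself ranked higher in transgenic fat. Of 22 adipocyte genes 3 rose: Pck1 (2.97-fold, log2 1.57, SE 0.16), Slc2a4 (1.67-fold, log2 0.74, SE 0.11) and Adipoq, the adiponectin gene (1.23-fold, log2 0.30, SE 0.06). Adjusted over the list alone 10 rose. The list mean was 11.62 ± 0.06 in wild-type and 11.84 ± 0.03 in transgenic fat (SD, n = 4), a full separation with an exact permutation p of 0.0286, the smallest that 4 against 4 arrays can give. Adjusted over the lists, the exact permutation p was 0.25. The camera adjusted p was 0.000277, and the adjusted p was 0.585 with an estimated correlation. The difference was 0.18, 0.21 and 0.24 within the plate columns and 0.19 in row G, where the row block ended the call. Because the list means separated fully, the sign of these values was fixed in advance. Lep, the leptin gene, differed by -0.06 (limma adjusted p = 0.596) and Pparg by 0.22 (adjusted p = 0.0834). The lipogenesis list (mean difference 0.08, camera adjusted p = 0.342) and the fatty acid oxidation list (0.07, camera adjusted p = 0.310) did not pass.

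Of 24 insulin and AMPK signalling genes 4 rose: Slc2a4, Prkag2, a regulatory subunit of AMPK (log2 0.42, SE 0.08), the adiponectin receptor Adipor2 (log2 0.30, SE 0.06) and Irs1, an insulin receptor substrate (log2 0.46, SE 0.09). Adjusted over the list alone 10 rose, and the list means separated fully (9.50 ± 0.04 against 9.68 ± 0.03, SD, n = 4; exact permutation p = 0.0286). Camera gave an adjusted p of 5.97e-05, and the adjusted p was 0.468 with an estimated correlation. The difference was 0.18, 0.16 and 0.22 within columns. The AMPK catalytic subunits Prkaa1 (log2 0.25, limma adjusted p = 0.0802) and Prkaa2 (log2 0.01) and the receptor Adipor1 (log2 0.10) did not pass. Prkaa1 was 0.29 and past the threshold without wild-type replicate 3, which had the highest wild-type value (10.19), so that its removal was bound to widen the difference.

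Mitochondrial genes ranked higher. Of 62 oxidative phosphorylation genes 7 rose, among them Uqcr11 of complex III (log2 0.57, SE 0.08), and Ndufb7 (log2 0.44, SE 0.08), Ndufa7 (log2 0.39, SE 0.07) and Ndufa12 (log2 0.29, SE 0.06) of complex I. Adjusted over the list alone 14 rose. The mean difference was 0.18 (exact permutation p = 0.0286; camera adjusted p = 2.11e-10, and adjusted p = 0.585 with an estimated correlation). Within columns it was 0.17, 0.10 and 0.25. Of 29 genes of the citric acid cycle and branched-chain amino acid breakdown 3 rose, all in branched-chain breakdown: Hibch (log2 0.46, SE 0.09), Bckdhb (log2 0.41, SE 0.07) and Dbt (log2 0.36, SE 0.07). The camera adjusted p was 2.16e-05, and the adjusted p was 0.718 with an estimated correlation; 7 rose when adjusted over the list alone. The row block ended that call, at 0.11 (adjusted p = 0.247), and within columns the difference was 0.13, 0.12 and 0.35.

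Cholesterol synthesis genes ranked lower, with 6 of 18 falling, among them Dhcr7, the last enzyme of the pathway (log2 -1.08, SE 0.16), Mvd (log2 -0.67, SE 0.10), Msmo1 (log2 -0.53, SE 0.09) and Mvk, mevalonate kinase (log2 -0.36, SE 0.05). Adjusted over the list alone 10 fell and 1 rose. The list means separated fully (8.98 ± 0.05 against 8.62 ± 0.18, SD, n = 4; exact permutation p = 0.0286), camera gave an adjusted p of 8.49e-09, and the adjusted p was 0.585 with an estimated correlation. The difference was -0.21, -0.61 and -0.32 within columns and -0.14 in row G.

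**Figure D2:**
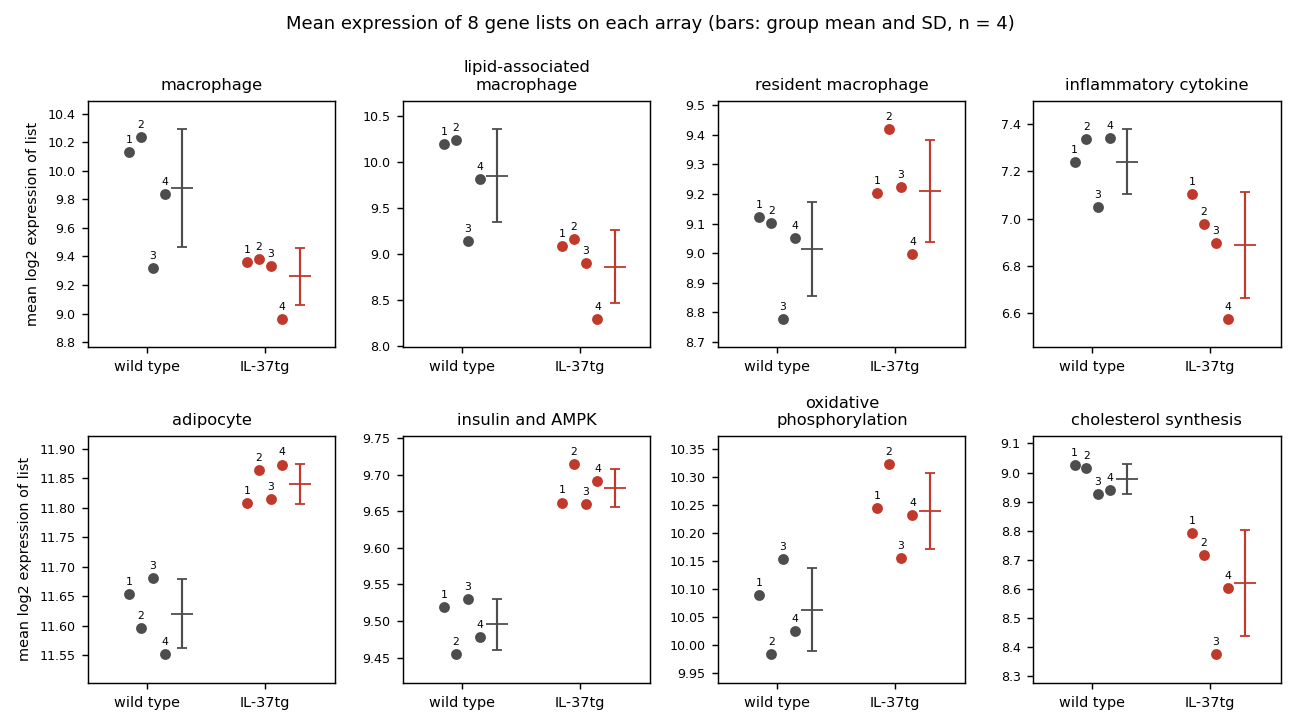
Mean log2 expression (vertical axes, a separate scale for each list) of 8 gene lists on each array, numbered by replicate; points are arrays, and bars give the group mean and SD of 4 arrays. The adipocyte, insulin and AMPK, oxidative phosphorylation and cholesterol synthesis means separated the groups, while wild-type replicate 3 lay among the transgenic arrays for general macrophage genes. For oxidative phosphorylation the groups only just separated, with wild-type replicate 3 at 10.153 and transgenic replicate 3 at 10.156.

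Cell cycle genes ranked lower, with Tpx2 (log2 -0.83, SE 0.17) the only 1 of 15 to fall over all genes tested and 9 falling when adjusted over the list alone (mean difference -0.69, camera adjusted p = 1.05e-07, and adjusted p = 0.585 with an estimated correlation). It differed by 0.11, -1.08 and -1.09 within columns and by -0.07 in row G, where the row block ended the call. Of 27 extracellular matrix genes Mmp14 (log2 -0.77, SE 0.15) and the collagen cross-linking Lox (log2 -0.72, SE 0.15) fell (camera adjusted p = 0.00046, and adjusted p = 0.718 with an estimated correlation; adjusted over the list alone 5 fell and 2 rose). The row block also ended that call, at -0.11, and within columns the list differed by 0.21, -0.31 and -0.49. 10 mast cell genes had no member past the threshold (mean difference -0.27, camera adjusted p = 0.0247, and adjusted p = 0.718 with an estimated correlation). Their call was lost without wild-type replicate 1 (-0.19), wild-type replicate 2 (-0.21) or transgenic replicate 1 (-0.17, adjusted p = 0.0953), and at or above the 25th percentile of gene means (-0.32, adjusted p = 0.064), and within columns they differed by 0.35, -0.39 and -0.56. 13 mesothelial genes likewise had none (mean difference 0.24, camera adjusted p = 0.0382, and adjusted p = 0.794 with an estimated correlation). Their call was lost without wild-type replicate 1 (0.19), wild-type replicate 2 (0.042, adjusted p = 0.233), transgenic replicate 1 (0.20), transgenic replicate 2 (0.19) or transgenic replicate 4 (0.21), and the difference was 0.38 without wild-type replicate 4. It was also lost after centring, with either filter on dim genes and with array weights (adjusted p from 0.0502 to 0.0638), and the difference changed sign with the plate row as a block, to -0.03. Within columns it was 0.06, -0.24 and 0.93.

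In all, 5 of 34 gene lists ranked higher and 8 lower with the preset correlation, and none with an estimated correlation. By fry, which asks whether a list moves 1 way on balance, the insulin and AMPK list and the adipocyte list passed (adjusted p = 0.00735 and 0.0448). Exact permutation p-values of lists were otherwise given unadjusted. Adjusted over the lists, they were 0.25 for the adipocyte, insulin and AMPK, oxidative phosphorylation and cholesterol synthesis lists. These lists therefore did not pass by the exact permutation test. Each was already at the smallest exact permutation p possible (0.0286), so the adjusted value decides nothing for or against them. Since their array means separated fully, the direction of their differences within columns and in row G was also fixed in advance. Other splits of the 8 arrays into 4 and 4 gave as many passing lists, up to 18, so the number of lists does not stand apart from chance, whereas no other split gave any gene past the threshold. Splits that exchange 1 array between the groups keep part of the real contrast. The evenly mixed split of wild-type replicates 1 and 3 with transgenic replicates 3 and 4 also gave 18 lists.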

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

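Tests chosen after the result was seen were those of the share of all leukocytes, the 2 arrays apart, transgenic replicate 4 alone, the plate row for macrophage genes, Nnt, small nucleolar RNAs without a measured host, the other RNA classes, the probe sets of Gm3893 and Fat3 and the distance to Cd72, and the later forms of the replicate 3 test; the others were chosen before. Of 330 groups of 4 arrays examined (named genes and list means), 18 had 1 array far from the other 3, or 5.45%, where chance gives about 1 in 20.

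The 18 arrays far from the others of their group were as follows, as log2 levels. In the transgenic group replicate 1 stood apart for Csf3r (5.88), Lcn2 (8.16), the T cell list (6.09) and the substrain list (7.77), and replicate 2 for Nnt (9.50). Transgenic replicate 3 stood apart for Adam7 (4.13), Bank1 (7.90), Kcnj16 (4.58), Krt7 (6.72), Otop1 (7.59) and the mesothelial list (7.82), and replicate 4 for Adgre1 (9.31) and the macrophage list (8.96). In the wild-type group replicate 1 stood apart for Retnla (10.26), replicate 3 for Dhcr7 (8.68), Mrc1 (10.29) and the immediate early list (7.31), and replicate 4 for Cxcl10 (8.34). Outside the gene table, 39 probe sets without a single gene symbol in the annotation used were higher in transgenic fat and 11 were lower, of 13904 tested with limma.

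The macrophage lists ranked lower in transgenic fat by camera, but not with an estimated correlation (adjusted p = 0.585 for the general and for the lipid-associated list), and their array means gave an exact permutation p of 0.114 and 0.0571. The resident macrophage list moved away from the general list by 0.82 log2 units (exact permutation p = 0.0286, the smallest possible), so macrophage genes did not all fall alike. A lower share of all leukocytes stays open, because higher Retnla (log2 1.33) and Cd163 (log2 0.77) per cell could hide it. The median of the resident list was 0.06, with 7 of its 16 genes below 0. A list of macrophage genes also does not cover other leukocytes. Of the lists for those, mast cell differed by -0.27 and passed by camera. T cell (-0.15), B cell (0.10), NK cell (-0.05), neutrophil (-0.01) and dendritic cell (0.02) did not pass. A list that did not pass does not show that the share of its cells was unchanged. A wrong label on wild-type replicate 3 was tested in 3 forms: 37 of 70 probe sets that separated the other 7 arrays by at least 1 log2 unit put it nearer wild type, or 52.9%, and so did 6 of 9 at least 2 units apart, which decided nothing, but the third form, chosen after both, argued against it, since replicate 3 lay within or beyond the transgenic range in 0 of those 9, and probe sets 10415081 (10.69 against a transgenic 4.97 ± 0.52, SD, n = 4) and 10468877 (8.69 against 3.94 ± 0.21) were at the wild-type level. Whether the 2 arrays apart (wild-type replicate 3 and transgenic replicate 4) shaped the difference was not decided. Without both it was -0.71, and the remaining wild-type means (9.84 to 10.24) lay above the remaining transgenic means (9.33 to 9.38). That separation was fixed once wild-type replicate 3, the only wild-type array inside the transgenic values, was left out, so it decides nothing. Removal of wild-type replicate 3 alone widened the difference to -0.81, so the size of the difference stays open too. How far it rests on transgenic replicate 4 also stays open. Without that array it was -0.52 (exact permutation p = 0.143, camera adjusted p = 4.15e-09) and -0.80 for the lipid-associated list (exact permutation p = 0.0857, camera adjusted p = 4.96e-08). The plate row cannot be told apart from the transgene, since the difference of -0.21 in row G rests on 1 transgenic array, and a true difference in macrophages between the lines remains an untested hypothesis.

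Small nucleolar RNAs were higher in transgenic fat, with 14 of 59 rising and 0 falling by limma, and they included Snora52 (log2 0.83, SE 0.07) and Snord15b (log2 1.03, SE 0.10), chosen after their values were seen. A matching rise in the measured RNA of the host genes was argued against for the 37 with 1 measured host, including 4 of the 14, because they moved away from their 33 hosts by 0.25 log2 units (exact permutation p = 0.0286, the smallest possible) and 0 hosts rose, but it stays open for the 22 others, with 10 of the 14. Transcription of the hosts was not itself measured, so it stays open. The plate row stays open: the difference in row G was 0.33 against a range of 0.07 between its 2 wild-type arrays, which met the bound set before, but that bound was wrong for 1 transgenic array, which excludes nothing, and within plate columns 5, 7 and 9 it was 0.41, 0.19 and 0.28. Of other RNA classes, 3 of 7 small nuclear RNAs rose and 0 fell (median log2 0.58, exact permutation p = 0.0286 for the class mean), 2 of 321 long noncoding RNAs rose and 0 fell (0.07, p = 0.0286), and 4 of 303 microRNAs rose and 1 fell (0.02, p = 0.83). A difference in recovery of short RNA between preparations stays open, since small nuclear RNAs moved up as well and the microRNA probe sets, with a median near 0, were dim (median level 4.26).

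In 35 of 35017 distinct probe sets the groups lay at least 1 log2 unit apart, including probe sets 10415081 (10.63 ± 0.11 against 4.97 ± 0.52, SD, n = 4) and 10468877 (8.73 ± 0.16 against 3.94 ± 0.21). Of 35 splits 1, the real split, gave as many and the highest other gave 2. That argued against chance but cannot exclude it, since 1 of 35 is the smallest share possible. The plate row, uneven over the same split, was not told apart from the transgene. The 35 probe sets are not 35 separate loci, since 8 carried the symbol Gm3893, alone or with others (2.25 to 2.79 log2 units higher), 6 carried Rnu2-10 and 2 Fat3, which leaves 22 with each of these counted once, and near-identical copies may be read by the same probes. A C57BL/6N-type background stays open: Nnt, a gene disrupted in the C57BL/6J strain, differed with an upper 95% limit of 0.34, but that lesion removes only some exons and nothing here places the probe set in them. Of the 7 measured genes of the substrain list, 0 passed by limma (list camera adjusted p = 0.987, fry adjusted p = 0.0678). Among them Entpd4 differed by 0.46 without overlap (limma adjusted p = 0.0684) and Cyfip2 by -0.26 (adjusted p = 0.148). Linked loci that differ between the lines also stay open: 0 neighbouring pairs (within 10 measured genes) were found among 11 genes, with Gm3893 counted once and 16 measured genes between it and Cd72, but random sets averaged 0.0573, so the bound set before, which took a lack of excess as evidence against, was wrong for so few genes. Sequence variants under the probes, which may also act on single probe sets, were not tested.

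For the number of genes, 1 of 35 splits, the real split with 629, gave as many and the highest other gave 0. That argued against chance but cannot exclude it, since 1 of 35 is the smallest share possible. The plate row, uneven over the same split, was not told apart from the transgene. For the number of gene lists chance stays open, since 11 of 35 splits gave at least 13 and the highest other gave 18.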

How the results depend on the processing

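The joint removal of wild-type replicate 3 and transgenic replicate 4 was chosen after the data were seen. All 629 genes kept their direction in every setting that tested them. Because their groups did not overlap, this was fixed in advance unless a setting changed the values themselves. It is therefore little evidence of stability. Still called were 569 without wild-type replicate 3, 446 without both arrays that stand apart, 347 without transgenic replicate 3, 81 to 214 without any other single array and 78 with the replicate number as a block. Counts of genes higher and lower were 741 and 554 at or above the median gene, where fewer genes were tested, 724 and 539 with array weights, 857 and 680 at an adjusted p of 0.10, and 162 and 158 with a log2 difference of at least 0.5 as well. They were 10 and 60 with the plate row as a block, 44 and 28 with the plate column, and 13 and 5 without the 2 transgenic arrays whose names end in 2, and of the 629 genes 15, 72 and 18 were still called. Without both arrays that stand apart 491 were lower (384 higher). Leaving out 1 array gave 50 to 520 higher and 32 to 668 lower. The share of higher calls, 62.0%, was 68.1% after centring, 43.8% without wild-type replicate 3 and 14.3% with the row block; for the array weights and the row block the cause was not tested. With the replicate number as a block 40 genes were higher and 53 lower. The correlations of same-numbered deviations were 0.09, 0.10, 0.09 and 0.06, not every array correlated best with its own number, and nothing in the labels pairs the arrays.

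Lists higher numbered 2 with the row block, 0 with an estimated correlation and 2 by fry, and lists lower 0 with an estimated correlation and 0 by fry; the set test itself differs there. Values that changed sign belonged to lists and genes that did not pass, except mesothelial, and the cause was not tested. With the row block they were antigen presentation 0.12, B cell -0.49 (adjusted p = 0.0344), NK cell 0.30, fatty acid oxidation -0.042, endothelial -0.018, mesothelial -0.030, epididymis and testis -0.30, ER stress 0.075, hypoxia 0.0025, substrain -0.23, Blk -0.0074, Eomes 0.11, Il18r1 -0.20, Il1b 0.32, Nnt -0.14, Prf1 0.00068 and Prkaa2 -0.11. With the column block they were neutrophil 0.036, hypoxia 0.0026 and Prkaa2 -0.011. Without the 2 arrays named with a final 2 they were dendritic cell -0.051, B cell -0.092, NK cell 0.0094, fibroblast progenitor -0.0084 and Nnt -0.072. With array weights they were antigen presentation 0.0035, NK cell 0.0043 and hypoxia 0.0015. After centring they were neutrophil 0.00038 and hypoxia 0.0080. At the 25th percentile filter they were neutrophil 0.077 and hypoxia 0.038. At the median filter they were hypoxia 0.045. Without both arrays that stand apart they were antigen presentation 0.040, neutrophil 0.075, hypoxia 0.0092, circadian 0.015 and Il1b 0.035. Leaving out 1 array in turn, the values ran from -0.056 to 0.069 for antigen presentation, from -0.023 to 0.070 for dendritic cell, from -0.073 to 0.38 for B cell, from -0.14 to 0.012 for NK cell, from -0.094 to 0.040 for neutrophil, from -0.051 to 0.094 for fibroblast progenitor, from -0.029 to 0.26 for epididymis and testis, from -0.019 to 0.0081 for hypoxia, from -0.059 to 0.022 for circadian, from -0.23 to 0.080 for Il1b, from -0.081 to 0.097 for Nnt and from -0.074 to 0.099 for Prkaa2. Of 73 named genes that did not pass, 17 moved by over 1.5 times or changed sign without 1 array and 41 passed in some setting; of 21 such lists, 20 moved and 6 passed. The B cell list passed in both directions, at -0.49 with the row block, 0.38 without wild-type replicate 3 (adjusted p = 0.00157) and 0.40 without both arrays that stand apart (adjusted p = 0.00413). The others passed in 1 direction, T cell in 4 settings (-0.21 to -0.15), lipogenesis in 2 (0.13 and 0.15), endothelial in 5 (0.12 to 0.16), interferon response in 3 (-0.18 to -0.13) and ER stress in 6 (-0.15 to -0.09). In the main setting these lists differed by -0.15, 0.08, 0.12, -0.09 and -0.09, in that order (camera adjusted p from 0.0668 to 0.342). Signal over background was not used here, so its limit on dim genes is unknown.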

Other observations

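The tests of the imprinted genes, and the 3 gene lists used in this part, were chosen after the values were seen.

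Of 22 genes of alternative macrophage activation 7 rose by limma and 15 did not pass. Those that rose were Rnase2a, Retnla, Ccl17, Cd163, the chemokine gene Ccl24 (log2 1.03, SE 0.14) and the lectin genes Cd209f (log2 0.89, SE 0.14) and Cd209g (log2 0.92, SE 0.19). Arg1 (log2 0.13), Mrc1 (log2 -0.37), Chil3 (log2 -0.27, with both means below 4.49) and Folr2 (log2 -0.08) were among those that did not pass. The list was written after its leading genes were seen and so its tests decide nothing about its direction (p = 0.0592 with an estimated correlation), and 9 of its genes stand in lists fixed earlier. More eosinophils are a candidate explanation, since Rnase2a and Ccl24 are tied to these cells, and the eosinophil list gave a camera p of 0.828, with Siglecf differing by 0.22 and Ccr3 by -0.20. That leaves the question open, because 5 of its 8 genes had means below 4.49, the 25th percentile of gene means.

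Neutrophil genes went both ways, with S100a8 (log2 -1.51, SE 0.27) and Csf3r (log2 -0.46, SE 0.07) falling and 1 rising, and the list of 12 did not pass (camera adjusted p = 0.232). Of 16 thermogenic genes Ebf2 rose (log2 0.45, SE 0.08), Otop1 fell (log2 -1.50, SE 0.19), and Ucp1, with both means below 4.49, differed by -0.41 (limma adjusted p = 0.390; -0.54 to -0.14 leaving out 1 array). The median of that list was 0.01 and its mean -0.15, and medians and means also differed in sign for antigen presentation (0.02 and -0.02) and dendritic cells (-0.03 and 0.02). Themis, a T cell gene, fell (log2 -1.56, SE 0.16), while the 17 T cell genes did not pass as a list (camera adjusted p = 0.0668).

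Imprinted genes may have risen together, a hypothesis drawn from the genes that passed. Of 26 imprinted genes 4 rose by limma, Nnat (log2 0.83, SE 0.08), Igf2 (log2 0.76, SE 0.16), Plagl1 (log2 0.75, SE 0.12) and Sgce (log2 0.45, SE 0.07), and 0 fell. Of those that did not pass, 3 had 95% limits above 0 and 4 had limits below 0, which were Zim1 (log2 -0.71), Igf2r (log2 -0.39), Dio3 (log2 -0.30) and Impact (log2 -0.17). The test missed its threshold (camera p = 0.0735, and p = 0.148 with an estimated correlation; exact permutation p = 0.114), so a coordinated rise was not shown, although a p above the threshold does not exclude it.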
